A study of Canis rufus and Canis latrans with 56 samples.

How the data were processed

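RNA was extracted from whole blood kept in RNAlater from 13 red wolves and 1 coyote, amplified, labelled with biotin and hybridised to human Illumina bead arrays, 4 arrays per animal. Signals were read with BeadStudio 1.5.0.34, per the submitters' processing notes. The deposited values are log2 intensities, which the authors, per the labels' design text, centred on the median of each array. In the table itself the mean of each array is 0 (largest absolute mean 3.24e-09), while the medians lie between -0.167 and -0.0325, so the values are relative to the mean. Their spread was not made equal between arrays: the 95th percentile of an array ran from 0.332 to 1.24. Whether a background was subtracted before the logarithm is not given in the sources used here, so fold differences are those of the deposited intensities. No detection p values were used here.

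The table holds 24354 probes and no missing value. The probe annotation gives 1 gene symbol for 18339 probes, several for 0 and none for 6015, with 16121 distinct symbols and 1589 genes on more than 1 probe. No canid genome was used, so no coordinates are given and the match of the human probes to canid transcripts was not examined. The animal, slide and position of each array were taken from the labels. The status (captive or free-ranging) and sex are not given for each animal in the labels used here, and no comparison by status or sex was made. A note on collection in the wild stands in the description of 1 array each of 3 wolves (11136, 111080 and 11310) and the coyote. The design text gives 7 free-ranging wolves, so a missing note does not mean captivity, and the note was not used as a group.

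Arrays of the same animal had a median correlation of 0.879 and arrays of different animals 0.839, across probes. No 2 arrays were identical, and the smallest SD of the difference of 2 arrays of an animal was 0.206. The nearest array by correlation was of the same animal for 31 of 56 arrays as deposited and for 42 after removal of slide means, where 3.05 are expected by chance. Slide differed in 4399 probes (animal kept in the model) and position on the slide in 109 (animal and slide kept), both at an adjusted p under 0.05. The 4 bacterial control probes had mean levels between -0.25 and 0.01. As a bound for background, the highest mean level among 39 measured genes of liver and skeletal muscle was taken, 0.396.

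All tests used limma 3.58.1 in R 4.3.3, with an intensity trend in eBayes and Benjamini-Hochberg adjustment at 0.05. Differences among the wolves were tested with the moderated F test of the animal terms over the wolves' arrays, with slide as a covariate; the 4 arrays of an animal measure array noise, and the test says whether animals differ by more than that. The share of variance between wolves came from the mean squares of animal and residual, and can fall below 0. For the coyote, a first fit of animal and slide gave 1 value per animal, and the coyote was compared with the 13 wolves on 12 residual degrees of freedom, its own spread being assumed to equal that of the wolves. Each of the 14 animals was also set against the other 13 in the same way.

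The 22 gene lists cover red cells, neutrophils, T cells, NK and cytotoxic cells, B and plasma cells, monocytes, platelets, eosinophils and basophils, interferon response, inflammation, glucocorticoid response, heat shock, oxidative stress defence, ribosomal proteins, oxidative phosphorylation, antigen presentation of class I and class II, proliferation, sex-linked genes, housekeeping genes, liver and skeletal muscle. Each gene was represented by its brightest probe. Lists were tested in the coyote comparison with camera at a preset correlation of 0.01, and among wolves by the median share of variance against 10000 random lists of the same size matched on level in 20 bins. The test among wolves asked only for a larger share, so a list with a smaller share than its random lists gets a high p value. A list score was the mean over members of the animal's value minus the wolves' mean, and 12 pairs of scores were correlated over the 13 wolves with 100000 permutations. All these choices were made before the data were examined.

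The wolf genes named are the 30 with a gene symbol, an adjusted p under 0.05 and a share of variance of at least 0.5 that had the largest SD over wolves. For the coyote, genes past the test and outside the range of all wolves were named, up to 10 per direction, and then those with the smallest p up to 5 per direction. Up to 4 members per list were named by the largest difference or SD; list members beyond these, TYROBP, and the genes given for wolf 11310 were chosen after their values were seen.

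The procedures were tested on simulated data with 200 changed probes of 24354. The changed probes were drawn at random from all probes, of which 8.47% lay above the background bound. The rates below therefore describe mostly dim probes, and recovery above the bound was not examined separately. The simulated lists were random genes drawn independently of each other, and their share of variance did not depend on level. Correlation among the members of a list and the matching on level were therefore not put to the test. The real ribosomal protein list had an estimated correlation of 0.038. The F test recovered 98% of probes with a between-wolf SD of 0.3 and 100% at 0.6, with 9 unchanged probes called. The coyote test recovered 97% of shifts of 1 and 99% of shifts of 2, with 8 unchanged probes called, and with no change 0 probes passed. On 16121 genes, camera called the shifted list (adjusted p = 3.70e-31) and the matched random lists called the raised list (adjusted p = 0.011), with 0 other lists called in either test.

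Alternatives were no slide term, slide and position, quantile normalization, 75th-percentile centring, scale normalization, leaving out dim probes (mean at or below the median of all probes), no intensity trend, a robust prior, all arrays in a fit with animal as a random block, the mean of a gene's probes, camera with an estimated correlation, fry, and leaving out animals, coyote arrays or slides in turn. Median centring, the restriction to probes or members above the background bound, and leaving out wolves for the wolf lists and for the relations were added after the data were seen. Figures were drawn with matplotlib 3.10.9.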

Results

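RNA from whole blood was measured in 13 red wolves (Canis rufus, an endangered North American canid) and 1 coyote. The labelled RNA of each animal was hybridised to 4 arrays, which gave 56 arrays on 7 slides of 8 arrays. The arrays carry 24354 probes for human transcripts, and a gene name below is that of the human probe; which canid transcript bound to it was not measured here. The 4 arrays of an animal share its labelled RNA and are technical, so each animal counts once. Values are log2 intensities relative to the mean of the array, and a difference of 1 is a 2-fold difference in intensity. The number of arrays limits the precision of each value.

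The probe of UBB, which encodes ubiquitin, had a mean log2 level of 8.14 ± 0.42 (SD, n = 13 wolves), that of the growth-related protein gene TPT1 6.79 ± 0.39, cytoskeletal actin ACTB 6.69 ± 0.32 and the ribosomal protein gene RPS14 6.51 ± 0.25. The levels of different probes depend on how well each human probe binds, and do not rank transcripts by abundance. The globin probe HBD stood at 6.21 ± 0.52, and HBB, the adult beta-globin gene, at 1.09 ± 0.20. The brightest of 39 measured liver and skeletal muscle genes, the haem carrier HPX, reached a level of 0.396, used below as a bound for background. Above it lay 2064 probes (8.47%), with 1597 named genes among them. Of the white cell markers, 1 of 23 measured neutrophil genes, 2 of 15 monocyte genes, 3 of 19 T cell genes and 0 of 16 B and plasma cell genes reached it. The monocyte genes were TYROBP and FCER1G, and FCER1G reached it only through the coyote.

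**Figure D1:**
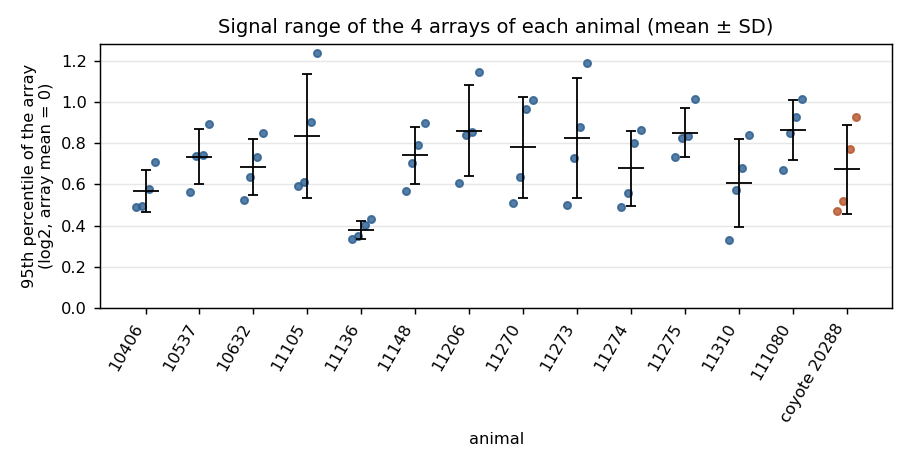
Each point is the 95th percentile of an array in log2 units (vertical axis, array mean set to 0) for the 14 animals on the horizontal axis, with the mean and SD of the 4 arrays as bars. Wolf 11136 had the lowest mean, 0.381 ± 0.044, and wolf 111080 the highest, 0.866 ± 0.145.

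The first comparison asked which transcripts differed among the 13 red wolves by more than their repeated arrays. MARCHF2, which encodes a membrane-bound ubiquitin ligase, had the largest SD over wolves, 1.77 against 0.27 between arrays. It stood at 4.08 in wolf 10537, 3.48 in wolf 11275, 3.23 in wolf 11273, 3.12 in wolf 11274 and 2.10 in wolf 10632, and between -0.37 and 0.01 in the other 8 wolves. EGR1, with an SD of 1.56 against 0.16 between arrays, had the largest F of all probes, 300.5 against 212.5 for MARCHF2. EGR1 and FOS, transcription factors that cells switch on within minutes of a stimulus, were highest in wolf 11310, at 5.48 and 4.68. The next highest wolf, 10537, had 1.83 and 2.33, and wolf 11273 was lowest for both, at -0.23 and 0.20.

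**Figure D2:**
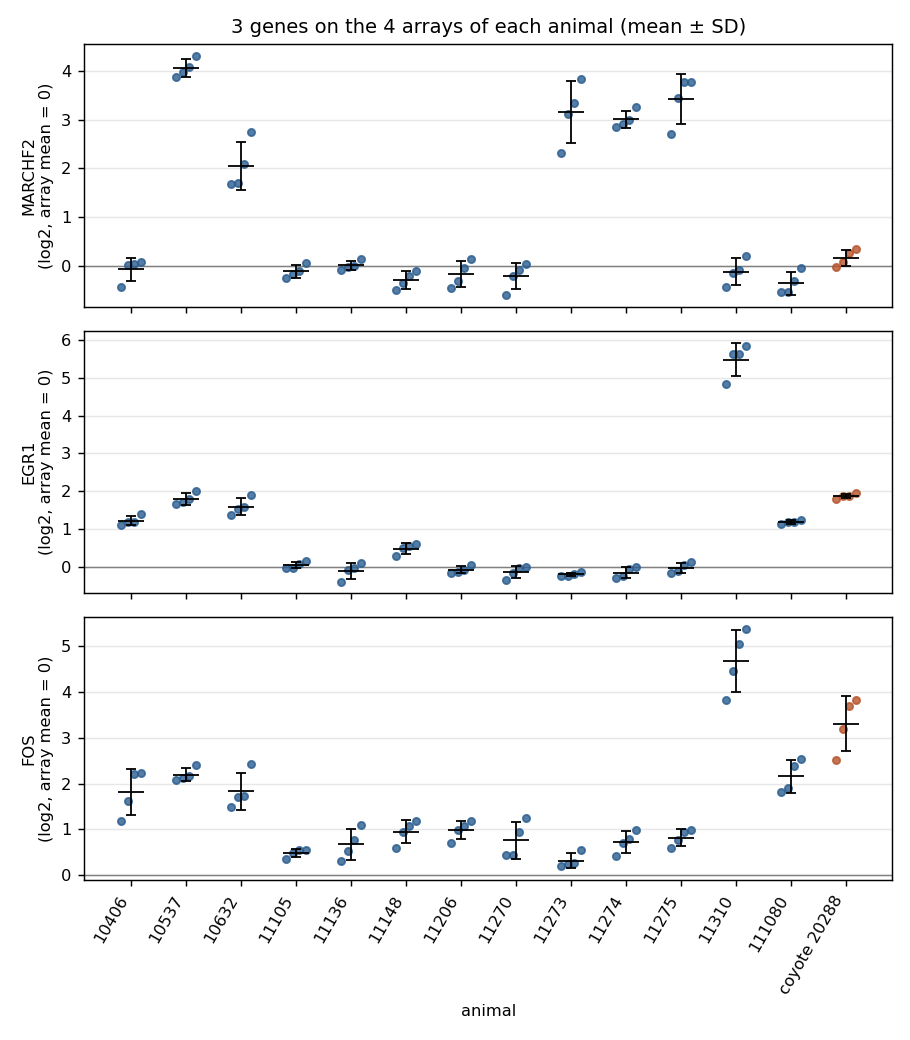
Points are the log2 levels of MARCHF2, EGR1 and FOS (vertical axes, array mean set to 0) on the 4 arrays of each of the 14 animals (horizontal axis), with mean and SD. MARCHF2 was well above 0 in wolves 10537, 10632, 11273, 11274 and 11275, and EGR1 and FOS were highest in wolf 11310.

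The actin-severing cofilin gene CFL1 had an SD of 1.18 and ranged from 0.64 in wolf 11136 to 5.34 in wolf 111080. The actin-binding genes LASP1 (SD 0.93), ARPC2 (0.90), CORO1A (0.87) and PFN1 (0.87) spanned 6.16-, 6.02-, 6.32- and 5.28-fold. CDA, cytidine deaminase, which is abundant in granulocytes, spanned 7.09-fold from wolf 11273 to wolf 111080. CEBPB, a transcription factor of myeloid cells, spanned 8.13-fold from wolf 10406 to wolf 11310, and GNAI2, a G protein subunit used by chemokine receptors, 6.73-fold. FLOT2, a membrane raft protein, spanned 7.43-fold, and GRAMD1A, a cholesterol transfer protein, 9.31-fold, both from wolf 11273 to wolf 11270. LGALS1, a galactose-binding lectin, spanned 11.9-fold from wolf 10406 to wolf 111080. NAMPT, an enzyme of NAD synthesis, had an SD of 0.88 and its lowest level, 0.25, in wolf 11273.

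Wolf 11136 had the lowest level of 8 of the 30 genes with the largest SD over wolves. CDC14B, a cell cycle phosphatase gene, stood at 0.10 there and between 2.72 and 5.51 in the other 12 wolves. RPL18, a ribosomal protein gene, stood at 2.03 against 5.09 on average in the others, and EEF1A1, a translation elongation factor, at 0.34 against 3.19. TSC22D1, a leucine zipper regulator, EMP3, a membrane glycoprotein, CFL1 and FKBP8, a mitochondrial chaperone, were also lowest in this wolf, at 0.10, 0.43, 0.64 and -0.19. GNAI2 stood at 2.48 there. The arrays of this wolf had the narrowest signal range.

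Of the rest of the 30, DHRS7 (a short-chain dehydrogenase), DDX5 (an RNA helicase), CHPT1 (phosphatidylcholine synthesis), TRIM8 (a ubiquitin ligase), HMGB2 (a chromatin protein), U2AF1 (a splicing factor), GAB2 (a signalling adaptor) and GAPDH (glycolysis) were lowest in wolf 11273, with SDs between 0.87 and 1.04. OGT, which adds N-acetylglucosamine to proteins, was lowest in wolf 11148 at 1.00 and highest in wolf 11206 at 3.64. Adjusted p values of limma's F test lay between 4.56e-45 and 9.99e-19 for these 30 genes, and all 30 passed under each of the 27 other settings tried on them.

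**Figure D3:**
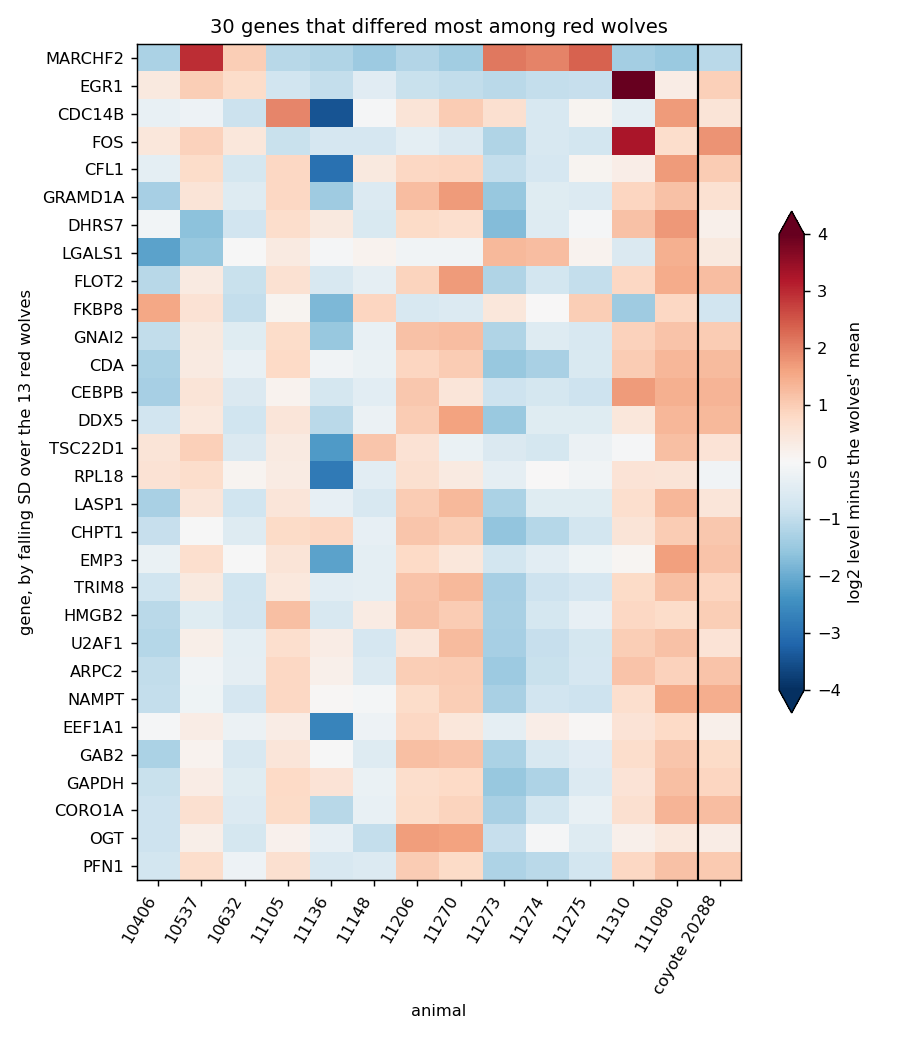
Colours give the log2 level minus the wolves' mean of the 30 genes with the largest SD over wolves (rows) in the 13 wolves and the coyote (columns, coyote right of the line). MARCHF2 is high in wolves 10537, 10632, 11273, 11274 and 11275, wolf 11136 has the lowest CDC14B, CFL1, RPL18 and EEF1A1, and wolf 11310 has the highest EGR1 and FOS.

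In all, 2732 of 24354 probes (11.2%) differed among the wolves in limma's moderated F test with slide in the model (adjusted p under 0.05), and these probes hold 2107 named genes. Of the 2064 probes above the background bound 78.1% passed (1613 probes), and of the others 5.02% (1119 probes). The share of variance that lay between wolves had a median of 0.0693 over all probes and 0.538 over probes above the bound, where it was 0.333 without the slide term. The test compares individual animals and says nothing of confinement. Of the wolves 6 were captive and 7 free-ranging, and status and sex are not given for each wolf in the labels used here. Wolves 11136, 111080 and 11310 carry a note of collection in the wild. Among them are 11136 and 11310, whose levels stood apart above, and any link to the note was not tested. With animal kept in the model, 4399 probes differed between slides, and slide was a term of each fit.

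Among the gene lists fixed beforehand, red cell genes differed among the wolves in 6 of 20 measured members (7 adjusted over the list alone). BNIP3L, which clears mitochondria from maturing red cells, had an SD of 0.81 and was highest in wolf 11274 at 4.33. HBD was highest in wolf 11273 at 6.85 and lowest in wolf 11310 at 5.41, and GATA1, the master regulator of red cell formation, and the alpha-globin gene HBA2 were highest in wolf 11105 at 1.04 and 1.43. Of the interferon genes 4 of 28 differed (4 over the list alone). OAS2, an antiviral sensor of double-stranded RNA, stood at 2.99 in wolf 11206 and 1.63 in wolf 11105. It stood at 1.40 in wolf 111080 and at 0.70 or lower in the other 10 wolves. The other members, OAS1, IFITM3 and OASL, were each lowest in wolf 11136, whose arrays had the narrowest signal range. Heat shock genes differed in 4 of 20 (5 over the list alone): the chaperone genes HSPA8 and DNAJA1 were highest in wolf 11310 at 4.07 and 2.52, and HSPH1 and HSP90AA1 in wolf 11273 at 2.64 and 1.05. Among glucocorticoid-responsive genes 3 of 15 differed (3 over the list alone), namely KLF9, a transcription factor, highest in wolf 11206 at 2.42, the receptor co-chaperone FKBP5, highest in wolf 11273 at 0.82, and CEBPD.

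Ribosomal protein genes differed in 20 of 68 members (23 adjusted over the list alone), led by RPL18, RPL27 (SD 0.58), RPL10A (0.53) and RPL27A (0.52). As a list they did not vary more than genes of their brightness: the median share of variance was 0.0889, against 0.120 for matched random lists. Genes of oxidative phosphorylation, the mitochondrial respiratory chain, differed in 15 of 69 (17 over the list alone), led by NDUFV2 (SD 0.73), ATP5F1A (0.63), ATP5F1B (0.50) and NDUFV1 (0.48). Housekeeping genes differed in 5 of 14 (6 over the list alone), with EEF1A1 and GAPDH at SDs of 0.88 and 0.87. In other lists the members that differed were 3 of 17 for NK and cytotoxic cells (GZMB, CTSW and NKG7), 2 of 19 for T cells (LCK and BCL11B), 2 of 23 for neutrophils (ALPL and NCF1), 2 of 15 for monocytes (FCER1G and AIF1), 2 of 17 for platelets (PF4 and TREML1), 2 of 12 for class I antigen presentation (PSMB10 and B2M), 1 of 16 for B and plasma cells (JCHAIN), and 1 of 9 for eosinophils and basophils (HDC). Adjusted over the list alone, these lists held 3, 3, 2, 2, 3, 3, 0 and 1. Of the members that differed, 2, 1, 1, 1, 1, 2, 0 and 1 had a mean level over the 14 animals above the background bound. GZMB, CTSW, NKG7, NCF1, PF4, B2M and HDC were lowest in wolf 11136, whose arrays had the narrowest signal range. The other members that differed in these lists were lowest in other wolves. For red cell, heat shock, ribosomal protein, respiratory chain and housekeeping genes the counts above the bound were 5, 3, 16, 13 and 4. No member of the inflammation, class II antigen presentation, sex-linked or liver lists passed (0, 0, 3 and 0 over the list alone), and 1 of 20 skeletal muscle genes did, ACTA1 (1 over the list alone).

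Genes of oxidative stress defence and of proliferation had a larger share of variance between wolves than random lists of equal size and brightness, with medians of 0.223 against 0.0803 (adjusted p = 0.022) and 0.180 against 0.0588 (adjusted p = 0.0198). In the first list 5 of 18 members passed the F test (8 over the list alone), 3 of them above the background bound. These 5 were SOD2, the mitochondrial superoxide dismutase, GCLC, which makes the first step of glutathione, PRDX1, GSTP1 and TXNRD1. In the second list only the cyclin gene CCNB2 passed (1 of 25, 0 over the list alone), and no member lay above the background bound. Both calls ended when dim probes were left out (adjusted p = 0.852 for each), with the mean of a gene's probes (0.0528 and 0.0803), and without wolf 11136 (0.290 and 0.0726); the other 20 lists had adjusted p values between 0.536 and 0.975. Leaving out wolf 11105, 11148, 11273 or 11274 also ended both calls, at adjusted p values of 0.423, 0.0763, 0.0968 and at least 0.0704, and wolves 11206, 11270, 11275, 11310 and 111080 ended the call of 1 list each.

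**Figure D4:**
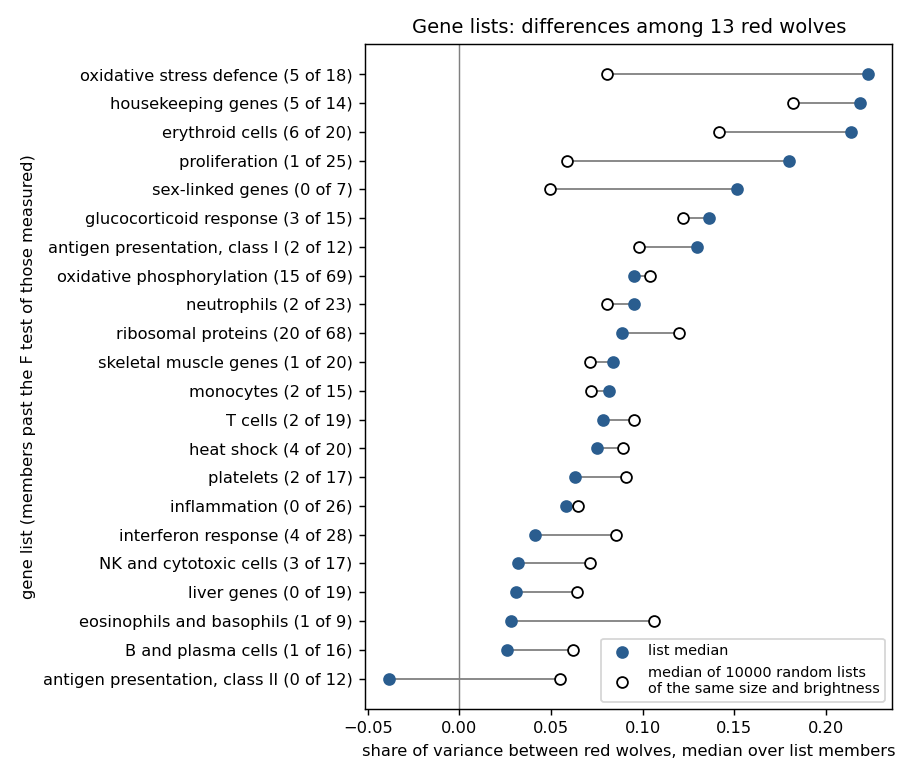
For each gene list (rows, with members past the F test and members measured) the filled point is the median share of variance between wolves over its members and the open point the median of 10000 random lists matched on size and brightness (horizontal axis, no unit). The filled point lies farthest to the right of the open one for oxidative stress defence, 0.223 against 0.0803, and proliferation, 0.180 against 0.0588.

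The mean levels of ribosomal protein genes and of respiratory chain genes went together over the 13 wolves. Their list scores had a Pearson r of 0.842 (permutation p = 0.00011, adjusted over 12 pairs 0.00132, two-sided) and a Spearman rho of 0.868 (permutation p = 0.00028, adjusted p = 0.00336). Without wolves 11148 and 11136, the farthest from the median, r was 0.839, and within the 7 slides it lay between 0.677 and 0.931. After quantile normalization, which gives each array the same distribution, r was 0.472 (adjusted p = 0.408).

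Neutrophil and monocyte scores ran in opposite directions, with r = -0.814 (permutation p = 0.00083, adjusted p = 0.00498) and rho = -0.681 (permutation p = 0.0124, adjusted p = 0.0746). The call, though not the sign, rests on wolves 11310 and 11273, since without them r was -0.550 (permutation p = 0.0781), and without wolf 11273 alone -0.712 (adjusted p = 0.0503). With all 13 wolves kept, the call was also lost with the mean of a gene's probes (r = -0.648, adjusted p = 0.0999). Within slides r ran from -0.844 to 0.289 and so did not hold in each, and with only the members above the background bound, 1 neutrophil and 2 monocyte genes (1 of them FCER1G), it was 0.253. The other 10 pairs, among them red cell genes with neutrophil or T cell genes and interferon genes with T cell genes, had adjusted p values between 0.0752 and 0.475. Several of these changed with only the members above the bound. The only neutrophil gene there was NCF1, at a mean level of 0.43, close to the bound. Red cell genes had r = 0.734 with NCF1 (permutation p = 0.00291, adjusted p = 0.0097), against 0.276 over all members of both lists. Glucocorticoid-responsive with neutrophil genes turned from -0.321 over all members to 0.605 with NCF1 (adjusted p = 0.0452). Both rest on a single gene and do not describe the neutrophil list. Interferon with T cell genes turned from -0.627 to 0.280 (adjusted p = 0.397). After quantile normalization interferon with T cell genes had r = -0.703 (adjusted p = 0.0376), and as reported r fell to 0.0349 without wolves 11206 and 11105.

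The second comparison set the coyote against the 13 red wolves. FCER1G, the gamma chain through which Fc receptors of myeloid cells signal, was 1.75 higher in the coyote on the log2 scale (SE 0.24; coyote 2.03, wolves 0.28 ± 0.32 SD, n = 13; limma adjusted p = 0.00132). The wolves' mean lay below the background bound, which 4 of the 13 wolves exceeded. The coyote stood 1.63 above the bound, a lower limit of its difference from the wolves below it. The coyote lay above the whole range of the wolves, -0.19 to 0.82, and on each of its 4 slides it exceeded the mean of the wolves by 1.48 to 1.99. Among the wolves FCER1G rose along their first principal component (r = 0.83, permutation p = 0.00053, rho = 0.742, permutation p = 0.00493), on which the coyote lay at the side of the higher levels. FCER1G is among the 2064 probes that define this component, admitted only through the coyote, and 35.4% of them had r of at least 0.5. Its p values against r = 0 therefore do not set it apart from the other probes. FCER1G was the only probe to pass, and the array holds 1 probe of this gene. A sequence difference under it between coyote and wolves cannot be told apart from a difference in expression. TYROBP, another signalling adaptor of myeloid cells, stood at 0.66 in the coyote and 0.56 ± 0.16 in the wolves (difference 0.10, SE 0.17).

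**Figure D5:**
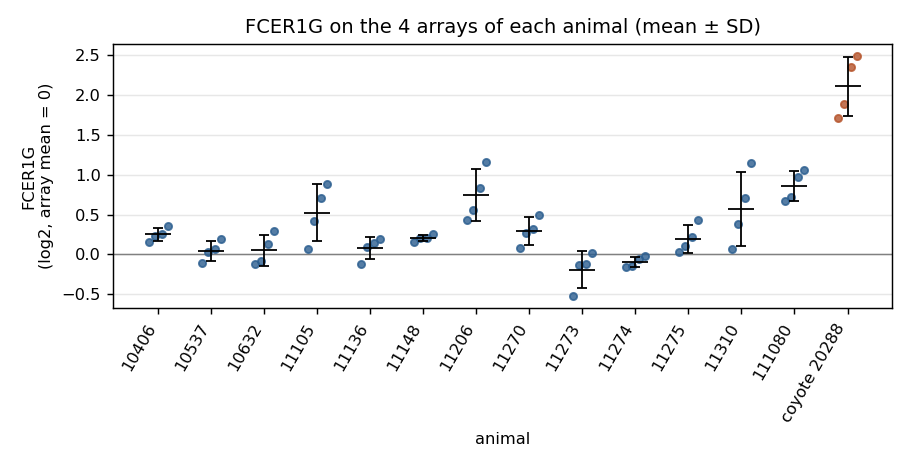
Points are the log2 levels of FCER1G (vertical axis, array mean set to 0) on the 4 arrays of each of the 14 animals (horizontal axis), with mean and SD. The 4 coyote arrays lie between 1.71 and 2.49, above the slide-adjusted levels of all 13 wolves, -0.19 to 0.82.

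No other gene passed, and the nearest ones are given as values. RBP4, the plasma carrier of retinol, stood at 0.82 in the coyote and 0.14 ± 0.13 in the wolves (difference 0.69, adjusted p = 0.0640). RBM7, an RNA-binding protein, AMZ2, a metallopeptidase, and SMAD3, a signal carrier of TGF-beta receptors, differed by 0.72, 0.57 and 0.35 (adjusted p = 0.530, 0.530 and 0.998). On the lower side were CD86, a costimulatory receptor of antigen-presenting cells (-0.37), the transporters SLC49A4 (-0.31) and SLC6A2 (-0.35), PHYH, an enzyme of peroxisomal fatty acid oxidation (-0.29), and ANLN, an actin-binding protein of dividing cells (-0.41), with adjusted p values between 0.530 and 0.998. The mean level over the 14 animals lay below the background bound for all 9, while in the coyote RBP4 and RBM7 stood above it, RBM7 at 0.86. The coyote stood 0.43 above the bound for RBP4 and 0.47 above it for RBM7, lower limits of its difference from wolves below the bound. For RBP4 0 and for RBM7 2 of the 13 wolves exceeded the bound.

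At an unadjusted p under 0.05, 910 probes differed, 457 higher and 453 lower in the coyote, where 1218 are expected by chance. This split moved both ways with the setting: 680 were higher and 301 lower with 75th-percentile centring, 173 and 324 with dim probes left out, and 358 and 502 without an intensity trend. Over all settings tried, the share of these probes that was higher ran from 34.8% to 69.3%. Outside the range of all wolves lay 12.2% of probes, and chance gives 14.3%. Among the 2064 probes above the background bound the share was 6.78% (140 probes), with 57 above the range and 83 below. Set in turn against the other 13 animals, the 14 animals gave between 569 and 2510 probes at an unadjusted p under 0.05. The coyote ranked 10th with 910, while wolf 11136 had 2510 and wolf 11206 had 1915. After adjustment wolf 11310 had 16 probes, wolf 111080 had 3, wolves 10632, 11136 and 11206 and the coyote had 1 each, and the other 8 wolves had 0.

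The FCER1G call was lost without the intensity trend of the variance prior (adjusted p = 0.298) and with a robust prior (0.848), where RBP4 passed in its place (0.0123). With 1 coyote, the comparison describes this animal and assumes that coyotes vary as the wolves did. The coyote carries a note of collection in the wild while 6 wolves were captive, so species was not separated from confinement. Differences of more than 1 did not pass for some genes above the bound. CYSTM1 stood at 4.36 in the coyote and 2.51 ± 0.83 (SD) in the wolves, and TBPL1 at 2.01 and 0.81 ± 0.40.

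Of the 22 gene lists, only ribosomal protein genes passed in the coyote comparison: 48 of 68 measured members were higher in the coyote, with a mean difference of 0.09 and a median of 0.06 on the log2 scale (camera with a preset correlation of 0.01, adjusted p = 0.00951). The call was lost with an estimated correlation (adjusted p = 0.358), with fry (0.551), with quantile normalization (0.0884) and with only the members above the background bound (0.114). None of its members passed alone, either over all probes or adjusted over the list alone; RPS9 stood at 5.37 in the coyote and 4.76 ± 0.48 in the wolves, RPL27 at 4.54 and 3.98 ± 0.58, and RPS10 at 3.55 and 3.02 ± 0.50. The mean shift was 0.06, 0.10, 0.08 and 0.15 within slides 1, 3, 4 and 5, and between 0.05 and 0.17 under the 5 scalings of the arrays. Single wolves lay as far from the wolves' mean. The list score was 0.087 in wolf 11206, 0.080 in wolf 11310 and -0.137 in wolf 11148, against 0.089 for the coyote. The size of the shift therefore does not set the coyote apart from single wolves.

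Monocyte genes were higher in 8 of 15 members (camera adjusted p = 0.0731; 1 member, FCER1G, passed, and 1 adjusted over the list alone). In fry's test for change in either direction the list had an adjusted p of 0.0251, and camera gave 0.0132 with dim probes left out. These values are not separate from FCER1G, a member that was 1.75 higher in the coyote. The list had a mean difference of 0.15 and a median of 0.06, and was not tested without that gene. The members above the background bound were FCER1G and TYROBP, and since FCER1G reached the bound only through the coyote, that setting was not read for this list. The list did not pass with an estimated correlation (0.358), in fry's test for change in 1 direction (0.429) or with quantile normalization (0.114). Housekeeping genes were higher in 11 of 14 (camera adjusted p = 0.0731). They passed with dim probes left out (0.00164), and did not with an estimated correlation (0.437), fry (0.551), quantile normalization (0.175) or only the members above the bound (0.114). The other 19 lists had adjusted p values between 0.431 and 0.992. For 10 of the 21 lists that did not pass, the median, the mean and the test did not share a sign. The mean difference of the housekeeping genes, 0.227, lay within the range of the wolves' own scores, which reached 0.244 in wolf 11206. Among B and plasma cell genes 1 member passed adjusted over the list alone and 0 over all probes; the remaining lists had 0 by either count.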

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

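Median centring, the restriction to probes or members above the background bound, and leaving out wolves for wolf lists and relations were chosen after the results were seen. Between wolves, the count of 2732 probes stayed within 1.5 times in 28 settings, and was 1790 with only the 2064 probes above the background bound, where fewer probes were tested. The median share of variance, 0.0693 (jackknife SE 0.0175), was 0.0461 with quantile normalization, 0.0475 with scale normalization, 0.114 with dim probes left out and 0.538 above the bound, and this last was 0.333 without a slide term. In the coyote comparison, 1 probe passed; 2 passed with slide and position removed, 75th-percentile centring, scale normalization or dim probes left out, 0 without an intensity trend, and 12 with animal as a random block. Leaving out a wolf gave 1 to 4 probes (4 without wolf 11310, 2 without 11136, 11148 or 111080), and leaving out a coyote array 1 to 2. FCER1G passed in 26 of its settings (the bound, met only through the coyote, among them) and RBP4, not called as reported, in 10, besides the random-block fit. That fit assumed a correlation of 0.0788 between arrays of an animal for all probes, where the median share of variance above the bound was 0.538. For coyote lists, 1 passed as reported, 0 with an estimated correlation, fry or quantile normalization, 3 with dim probes left out (monocytes, ribosomal proteins and housekeeping genes), and 1 to 2 without a wolf (2 without 11206). With members above the bound ribosomal proteins did not pass (adjusted p 0.114), and the monocyte list was not read, since FCER1G reached the bound only through the coyote. For wolf lists, 2 passed as reported, 0 with the mean of probes, dim probes left out or members above the bound, and 0 to 2 without a wolf (0 without 11105, 11136, 11148, 11273 or 11274). Of relations, 2 passed as reported, 1 without the 2 farthest wolves or with the mean of probes (neutrophils with monocytes lost in both), 7 of 10 with members above the bound, and 1 to 3 without a wolf (1 without 11273, 3 without 10632 or 11136). The correlation of neutrophils with monocytes was 0.25 with members above the bound. Except where a smaller number of probes or members shows it, the cause was not tested. No value was missing, so keeping only complete probes moved nothing. The low signal over background, with 8.47% of probes above the bound, limits the white cell lists: 1 neutrophil gene and 2 monocyte genes lay above it. No paired analysis was possible because the 1 coyote shares no animal number with the wolves; slides were shared, and slide was a term of the fits.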

Other observations

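The tests of components, of MARCHF2 and of wolf 11136 were chosen after the results were seen, and the exchange of animal labels was set before. Wolf 11310 had 16 probes that differed from the other 13 animals (limma adjusted p under 0.05), all higher. EGR1 and FOS, the early transcription factors, were higher by 4.90 and 3.38 on the log2 scale (SE 0.58 and 0.66, adjusted p = 3.77e-05 and 0.0337). ATG3, an autophagy enzyme, was higher by 1.34 (SE 0.26). For the following 6 genes the mean of the other animals lay below the background bound, and the differences are given from the bound. They are lower limits only against animals below it. The bound was exceeded by 3 of the 13 others for AZIN1 (the coyote at 1.21), 5 for CIRBP and 0 for each of the rest. DYNLL2, a dynein light chain, was at least 1.40 higher, and CIRBP, a cold-inducible RNA-binding protein, at least 1.2. Of AZIN1, a regulator of polyamine synthesis, 1 of 2 probes was at least 1.38 higher. The other AZIN1 probe had 1.03 ± 0.24 (SD) over the 13 wolves and was not called for wolf 11310. The rise in AZIN1 therefore holds for 1 probe only. GADD45B, a stress-response gene, TNFRSF17, a plasma cell receptor, and TRIB1, a pseudokinase, were at least 0.32, 0.35 and 0.06 higher. Of these, all but AZIN1 had a mean level over the 14 animals below the bound. The coyote had 1.82 for EGR1 and 3.21 for FOS, and the highest of the other wolves 1.83 and 2.33.

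The first principal component of the wolves, over the 2064 probes above the background bound, held 54.0% of the variance, and the second 23.5%. On the first, wolves 11206, 11310, 111080 and 11270 had scores between 14.5 and 16.1, the projected coyote 12.5, and wolf 11273 -17.3. Among named genes GRAMD1A, FLOT2, CDA and LASP1 had the largest positive loadings, and MARCHF2, BNIP3L, CD276 and FKBP8 the largest negative ones. Wolf 11136 had 19.7 on the second.

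Along this component 35.4% of probes had r of at least 0.5 and 12.8% had r of -0.5 or lower. A wider signal range of some arrays may account for the first share but moves bright probes 1 way, and 12.8% lies between the limits set for and against it; the 95th percentile had r = 0.214 with the component (permutation p = 0.494, rho = 0.313, p = 0.297, 0.0863 without the 2 farthest wolves). A shifting share of red against white cell RNA would move the marker lists apart. The 7 red cell genes all had negative r, between -0.703 and -0.233, with a median of -0.367. The 10 white cell genes had a median r of -0.166, with 4 above 0 and 6 below. As a set they did not rise as this explanation requires. Among the 4 is FCER1G, which reached the bound only through the coyote. The limit set against the explanation concerned the red cell genes alone, so the white cell genes could not decide it and it stays open. HBD had r = -0.703 (permutation p = 0.0104, adjusted over 2 relations 0.0208, over 3 with FCER1G 0.0156, rho = -0.659, p = 0.0162). The call, though not the sign, rests on the 2 farthest wolves (r = -0.572 without them, p = 0.0707). FCER1G, a white cell gene called in the coyote, had r = 0.83 (permutation p = 0.00053, adjusted over 3 relations 0.00159, rho = 0.742, p = 0.00493, r = 0.735 without the 2 farthest wolves), and the coyote lay at 12.5. HBD and FCER1G are among the probes that define the component, so their p values against r = 0 do not set them apart from the other probes. The 4 wolves with higher scores than the coyote had FCER1G levels of 0.82 or less against 2.03 in the coyote. Captivity, free range and sex stay open, untested, since they are not given per animal in the labels used here.

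MARCHF2 lay between -0.37 and 0.01 in 8 wolves and between 2.10 and 4.08 in 5. The amount of red cell RNA as the whole cause is argued against by 2 wolves, 10406 and 11105, whose mean over the 7 red cell genes above the bound was 0.28 and 0.46 over the wolves' mean, against 0.02 in wolf 10537, and whose MARCHF2 was -0.16 and 0.01. A sequence difference under the probe may also give such a split and cannot be told apart from a difference in expression, since 0 further probes of the gene were on the array.

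Wolf 11136 had 14 probes at least 1 log2 unit below every other wolf, and each other wolf had 0. A single array or slide as the whole cause is argued against by leaving out each of its 4 slides in turn: of the 12 to 18 probes that met this limit without a slide, 100% lay below the other wolves' mean on that slide (lowest exact 95% bound 73.5). This replaced a test on the 14 probes themselves. The exact bounds in this paragraph count probes as independent. The probes share the labelled RNA of this wolf, so the bounds do not measure a spread between samples. A narrowing of the signal on its arrays may account for part of the pattern and stays open: 50% of the probes (7 of 14, exact 95% interval 23.0 to 77.0) remained so after quantile normalization and 78.6% after scale normalization. The test by quantile normalization replaced an earlier one, in which 15.4% of 240 bright probes reached the other wolves' median and 0 lay above every other wolf. RNA quality was not tested.

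For the 2732 probes that differed among the wolves, animal labels were exchanged within slides. Of 100 splits, the real one included, 1 gave as many probes, and the highest of the others gave 139, so chance can be excluded for the count as far as array noise within slides goes. Differences that arose when the RNA of each animal was prepared were not tested.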
